A study of Rattus norvegicus with 6 samples.

How the data were processed

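The series measured messenger RNA in Rat-1 cells, an established rat fibroblast line, 4 h after 25000 cells per well were seeded on extracellular matrix (ECM). The matrix was left native or had been remodelled by matrix metalloproteinase 1 (MMP1) or matrix metalloproteinase 13 (MMP13), both secreted collagenases. Per the labels' protocols, adherent cells were lysed on the matrix, total RNA was extracted with a column kit, and 3' end libraries were made in which the second read carried a random molecular identifier (UMI) of 8 nucleotides. The 6 libraries form 3 groups of 2, and group and replicate number were taken from the sample titles. The labels call the samples duplicates and do not say whether these were separate cultures of separate days. The p-values therefore rest only on spread between these libraries, which may be technical. In the main gene test this spread was pooled over genes of like level and was not the gene's own.

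One deposited table of 17143 genes with 1 column per library was analysed. Per the submitters' processing notes, bcl2fastq, TopHat and DESeq were used, with no versions, on the rat build rn5. The gene counter, the annotation release, strand use and the collapsing of UMIs are not given in the sources used here. The deposited values are a normalized signal: gene counts that the authors divided by 1 size factor per library. This was read from the values themselves. In each library 100% of values above 0 were whole multiples of the smallest one, within a tolerance of 0.01 reads, so whole reads could be recovered. Recovered totals ranged from 161817 to 362122 reads per library, and 1 read was worth between 0.735 and 1.68 normalized units. A gene at 0 could still hold up to 3 reads, that is 2.21 units in the deepest library and 5.04 units in the shallowest. If UMIs were not collapsed, reads are not independent molecules, and such floors cover counting error only. Of the genes, 2408 had no read in any library. Symbols were used as deposited. Of these, 16729 (97.6%) matched a RefSeq table of the assembly GRCr8 by symbol or synonym. That table served only for synonyms and gene spans, and because the builds differ no coordinates are printed.

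Differential expression was tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend), with 1 coefficient per group, all 6 libraries in the fit and no replicate block, which left 3 residual degrees of freedom. Genes with a value of at least 5 in at least 2 libraries were tested (7284 genes). A call is a Benjamini-Hochberg adjusted p under 0.05. Unless another tool is named, every adjusted p for a gene is from this limma fit. The design assumed counts as 1 possibility and normalized values as another, and the branch for normalized values was followed. Folds are on the log2(value + 1) scale, which understates changes of low genes. The prior degrees of freedom were estimated as infinite, so each gene's spread was taken wholly from the trend at its level and not from its own libraries. The gene tests thus ran on 21852 degrees of freedom, pooled over genes, and not on 3. A gene whose replicates scatter more than the trend therefore gets too small an error. Library values are given for some such genes only, so genes without them may scatter as much. For example, without native replicate 1 or 2 the log2 fold of Rpl23a on MMP1-treated matrix was 0.71 or 1.46. That of Slc38a2 on MMP13-treated matrix was -0.46 or -1.19.

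The recovered reads were also tested, as alternatives chosen after seeing the data, with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, 4574 genes) and DESeq2 1.42.0 (Wald test). The independent filtering of DESeq2 left 858 genes to adjust over for MMP13 against native and 14735 for each other comparison. In advance, 31 gene lists were fixed. The 21 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over lists within a comparison. The genes named were also set by a rule fixed in advance. The rule took, per comparison and direction, the 8 largest folds among calls whose libraries did not overlap between groups and whose mean level was at or above the median of tested genes (13.3 units). Where fewer than 3 qualified, the smallest unadjusted p filled up to 3. Up to 4 members of each called list and up to 2 of any other list were named by smallest p. Mmp13, Mmp3, Timp1, Col1a1, Acta2, Ctgf and Cyr61 were always given, and 1 further gene of this group is not reported here. Predicted genes with LOC or RGD numbers (710 in the table) were counted and not named. Junb, Sqstm1, Akr1b8, Ppm1g, Rpl37a, Rpl41, Mip, Txnrd1, Hnrnpa2b1, and Ahnak and Nme2 on the MMP13-treated matrix, were named after their values were seen.

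The scripts were tested on simulated counts drawn for the real genes at the real depths with a common dispersion of 0.0394. For MMP1 against native, with 7085 genes tested, 3 of 200 genes changed 2-fold were recovered. With 7052 genes tested, 128 of 200 genes changed 4-fold were recovered, and 90.7% of those above the median level, with 4 false calls. Over 100 draws with no change, the mean number of calls was 0.09 for MMP1 against native, 0.04 for MMP13 against native and 0.13 for MMP1 against MMP13. These simulations assume 1 dispersion for all genes and do not cover genes that vary more.

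Alternatives set before the data were examined were limma without the trend, TMM and quantile scaling, no filter, a stricter filter (20 units in every library of a group), a pseudocount of 5, a replicate block, a fit of only the 2 groups compared, an adjusted p under 0.1, and leaving out each library in turn. Size factors of the DESeq type in place of TMM were meant for raw counts only and were not run as a separate setting, since the deposited values already carry 1 size factor per library. Alternatives added after seeing the data were edgeR, DESeq2, TMM factors from all genes in the table, genes with identical values counted once, the oxidative stress list without Hmox1, and quantile scaling of the list tests and of the shared response. Among tested genes, 68 in 19 sets had the same reads as another gene in every library, so the same reads were counted under several names. Ribosomal protein genes have many near-identical copies in the genome, and their values are uncertain where reads could be split among copies. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.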

Results

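Transcript levels were measured by 3' end sequencing in Rat-1 fibroblasts 4 h after seeding on native ECM (2 libraries), on ECM remodelled by MMP1 (2 libraries) and on ECM remodelled by MMP13 (2 libraries). The design asked how the fibroblasts' transcription responds to a matrix degraded by either protease, with the native matrix as control. Values are the deposited size-factor-normalised reads, called units here. Recovered reads numbered 219775 and 347618 in the native libraries, 184061 and 225105 in the MMP1 libraries, and 362122 and 161817 in the MMP13 libraries. Between 9983 and 10852 genes had at least 1 read in a library.

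The most abundant transcripts included those of fibroblasts, such as Actb (mean 4231 units), Col1a1 (2094), Lgals1 (1638) and Vim (1308). Marker lists of 9 other cell types or tissues (tenocyte, leukocyte, endothelial, epithelial, erythroid, muscle, adipocyte, cartilage and Schwann cell) each took at most 0.0299% of reads in any library. Each had fewer than 5 tested members and entered no list test. The entry Rn45s, named for the ribosomal RNA precursor, took 0.320% ± 0.038 of reads on native matrix, 0.80% ± 0.19 on MMP1-treated matrix and 0.83% ± 0.20 on MMP13-treated matrix (SD, n = 2 each). Whether its reads came from the precursor or from mature ribosomal RNA was not checked. Replicates differed by more than sampling noise in each group, with a chi-square per degree of freedom of 2.54 in native, 2.10 in MMP1 and 2.29 in MMP13 libraries. Across the 7284 tested genes, log2 values of replicates correlated with r between 0.809 and 0.849. Libraries of different groups correlated with r between 0.772 and 0.884, so these correlations did not separate the groups. The highest joined the 2 deepest libraries, MMP13 replicate 1 and native replicate 2. Read noise of low genes enters these values, which therefore cannot show whether the groups separate beyond it. Genes are not independent replicates in these correlations.

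On MMP1-treated matrix, 10 genes were higher and 1 was lower than on native matrix. Hmox1, the haem oxygenase induced by oxidative stress, rose from 148 ± 26.8 to 328 ± 37.9 units (SD, n = 2 each), a log2 fold of 1.15 (SE 0.16, adjusted p = 5.3e-10). Thioredoxin Txn1 rose by a log2 fold of 0.94 (SE 0.20), from 83.9 and 154 units in the native libraries to 223 and 215. The stress-inducible early gene Ier3 rose from 57.5 ± 4.0 to 125 ± 25.7 units, a log2 fold of 1.09. The largest folds were of the taurine transporter Slc6a6 (log2 fold 2.81, SE 0.66; 1.22 and 6.04 units on native, 20.4 and 34.8 on MMP1) and the folate-polyglutamating enzyme Fpgs (2.33, SE 0.51; 2.43 and 17.4 units against 39.4 and 38.4). Both folds leaned in part on native replicate 1, where both values lie under the 3.65 units that 3 reads make in that library. Without that library the log2 fold was 1.98 for Slc6a6 and 1.12 for Fpgs. Rn45s rose by a log2 fold of 1.33, from 927 and 768 units to 1777 and 2529. The ribosomal protein genes Rpl23a (1.09), Rpl7 (0.86) and Rpl41 (0.57) were also higher, as was Mip (0.33), which encodes the lens membrane protein aquaporin 0. Whether the reads counted under Mip came from that gene or from a neighbouring or repeated sequence was not checked here, since no annotation of the build rn5 was used. The gene that fell was Ahnak, encoding a very large scaffold protein, from 637 ± 3.3 to 434 ± 25.7 units (log2 fold -0.55, SE 0.13, adjusted p = 0.029). The next lower genes, Nme2 (log2 fold -0.46, adjusted p = 0.085) and the complex III subunit Uqcr10 (-1.39, adjusted p = 0.085), did not pass, though Nme2 did with quantile scaling (adjusted p = 0.0264).

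Of the 21 lists tested in this comparison, 3 passed by camera, all in the higher direction. In the oxidative stress list of NRF2 targets and metal-response genes (adjusted p = 6.3e-04), 2 of 16 members passed, Hmox1 and Txn1, and 4 when adjusted over the list alone. The list's adjusted p was 0.71 with an estimated correlation. The peroxiredoxin Prdx1 (log2 fold 0.50, adjusted p = 0.13) and the ferritin light chain Ftl1 (0.56, adjusted p = 0.37) were the next members. Prdx1 passed with quantile scaling (adjusted p = 0.0424) and without native replicate 2 (0.0252). In the ribosomal protein list (adjusted p = 2.6e-04), 1 of 33 members passed, Rpl7, and the list's adjusted p was 0.70 with an estimated correlation. Adjusted over the list alone, 4 were higher and 1 lower. Among its members, Rpl35 had a log2 fold of 0.75, Rps14 of 0.94 and Rps18 of -0.55, and the list's median log2 fold was 0.25. In the immediate-early list (adjusted p = 0.041), 1 of 22 members passed, Ier3, and 3 adjusted over the list alone. With an estimated correlation this list too had an adjusted p of 0.70. There Junb had a log2 fold of 0.58, Ier2 of 1.01 and Btg2 of 0.77. Fry called no list in this comparison. The Rn45s share was 0.320% on native and 0.80% on MMP1-treated matrix, in the same direction as these 3 lists. Without Hmox1 the oxidative list had an adjusted p of 0.0611, and without MMP1 replicate 1 it had 0.0517. The immediate-early list had an adjusted p of 0.54 without MMP1 replicate 1, 0.0501 without MMP13 replicate 1 and 0.28 without native replicate 2. The other 18 lists had adjusted p of at least 0.63. Over all alternatives the adjusted p of the oxidative list ran from 1.1e-04 to 0.71, that of the ribosomal list from 3.6e-05 to 0.70 and that of the immediate-early list from 0.034 to 0.70.

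At an unadjusted p under 0.05, 600 genes differed in this comparison. By edgeR 9 genes were higher and 1 lower, 10 of these shared with limma. DESeq2 called 1 higher, Hmox1, and 0 lower, and limma without its trend called 0. Quantile scaling gave 11 higher and 3 lower. The count of higher genes was 5 without MMP1 replicate 1, 3 without MMP1 replicate 2, 3 without native replicate 1 and 15 without native replicate 2. Of the 11 calls, those of Hmox1 and Rn45s held without each of the 6 libraries in turn, those of Mip, Rpl41 and Rpl7 in 4 of these fits, those of Fpgs, Ier3, Rpl23a and Txn1 in 3 and that of Slc6a6 in 2. The log2 fold of Txn1 was 0.51 without native replicate 1, and edgeR gave Fpgs an adjusted p of 0.062. DESeq2 gave Rn45s an adjusted p of 0.084, and over all alternatives its adjusted p ran from 2.9e-50 to 0.70. The count of lower genes was 2 without MMP1 replicate 1, 4 without MMP1 replicate 2, 0 without MMP13 replicate 2, 0 without native replicate 1 and 2 without native replicate 2. Ahnak passed without MMP13 replicate 1 and in no other fit that left out a library, and its adjusted p over all alternatives ran from 0.012 to 0.77.

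**Figure D1:**
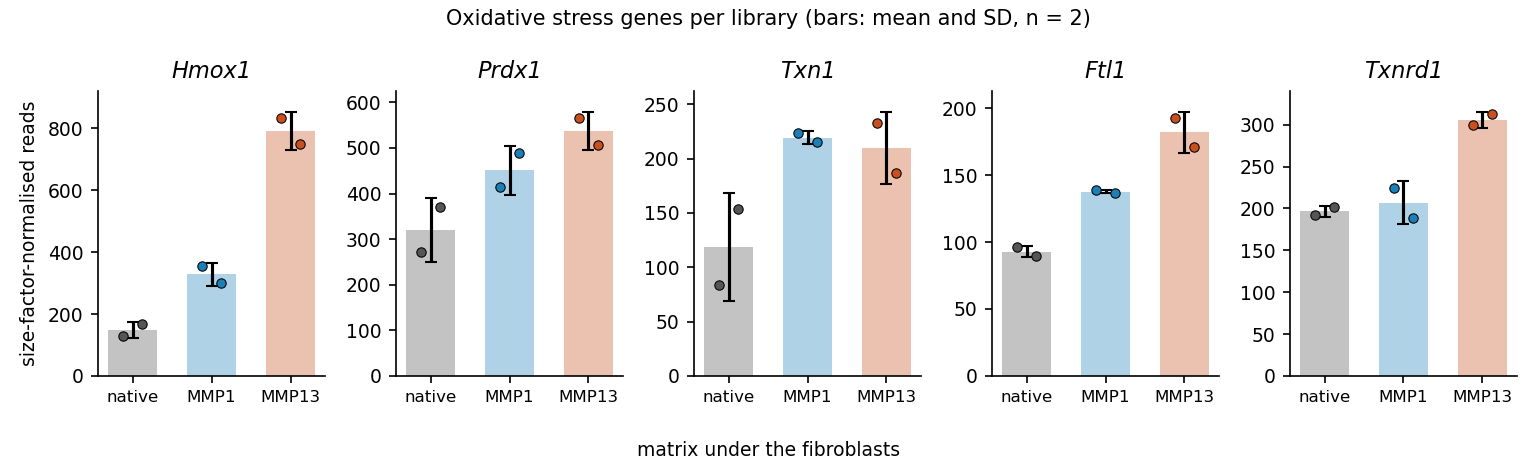
Size-factor-normalised reads (vertical axes, linear from 0) of 5 oxidative stress genes on native, MMP1-treated and MMP13-treated matrix. Points are libraries, bars are means and whiskers the SD (n = 2). Hmox1 lies at 129 and 167 units on native, 355 and 301 on MMP1-treated and 835 and 749 on MMP13-treated matrix, while Txnrd1 lies at 192 and 201 units on native and 225 and 188 on MMP1-treated matrix.

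On MMP13-treated matrix, 20 genes were higher and 10 lower than on native matrix. Hmox1 rose to 792 ± 60.7 units from 148 ± 26.8 (SD, n = 2 each), a log2 fold of 2.42 (SE 0.16, adjusted p = 2.0e-50), or 5.36-fold. Other antioxidant and iron-storage genes rose with it. Prdx1 went from 321 ± 70.3 to 537 ± 41.8 units (log2 fold 0.76, SE 0.14), Ftl1 from 92.9 ± 4.4 to 182 ± 15.1 (0.96, SE 0.22) and Txn1 from 119 ± 49.5 to 210 ± 33.0 (0.87, SE 0.20). The autophagy receptor gene Sqstm1 (log2 fold 0.67), the aldo-keto reductase gene Akr1b8 (0.65) and the small heat shock protein gene Hspb1 (0.70) also passed. Of the early genes, Ier2 had a log2 fold of 1.46, Ier3 of 1.13 and the AP-1 subunit gene Junb of 0.72. Rn45s (log2 fold 1.38; 927 and 768 units on native, 1844 and 2631 on MMP13) and Rn28s (1.32; 77.8 and 99.6 units against 282 and 175) rose. So did the ribosomal protein genes Rpl7 (1.03), Rpl35 (0.88), Rpl41 (0.51) and Rpl37a (0.60). Rpl37a carried the same reads as the pseudogene entry Rpl37a-ps1, and these 2 calls rest on 1 set of reads. Fam65b (1.09), the phosphatase gene Ppm1g (0.94) and Mip (0.30) completed the higher genes. The libraries of Mip overlapped between the groups, at 5819 and 4880 units on native and 5674 and 7543 on MMP13-treated matrix. The adjusted p was 0.0499 for Hspb1, Ppm1g and Rpl37a and, among lower genes, for Ahnak, Nme2 and Rab18. With genes of identical reads counted once, it was 0.0510 for each of these, and 16 higher and 7 lower genes were left.

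The genes lower on MMP13-treated matrix included Mmp9, which encodes a secreted gelatinase, at 54.7 and 20.4 units on native and 18.4 and 3.36 on MMP13-treated matrix (log2 fold -1.91, SE 0.48, adjusted p = 0.030). The adjusted p of Mmp9 was 0.996 without MMP13 replicate 2, 0.999 without native replicate 1, 0.0660 and 0.082 without MMP1 replicates 1 and 2, 0.109 by edgeR and 0.83 without the limma trend, over a range of 4.0e-04 to 0.999, and its log2 fold ran from -2.98 to -0.83 with a library left out. The call was also lost with no filter, the stricter filter, a pseudocount of 5, only the 2 groups compared and TMM factors from all genes. Nfat5, a transcription factor of the osmotic stress response, went from 53.7 ± 7.2 to 20.8 ± 15.2 units (log2 fold -1.52), but had an adjusted p of 0.103 by edgeR and a log2 fold of -0.74 without MMP13 replicate 2 (adjusted p = 0.996). Nfat5 kept its call in 2 of the 11 alternatives with all libraries that gave it an adjusted p, Rab18 in 1, and Ppp6r1, Vps25 and Bloc1s4 in 3 each. The amino acid transporter gene Slc38a2 had a log2 fold of -0.83 and the endosomal sorting gene Vps25 one of -1.36. The phosphatase regulator gene Ppp6r1 (-1.41), Ubl3 (-1.93), the GTPase gene Rab18 (-2.17) and Bloc1s4 (-2.44) had mean levels of 42.3, 28.0, 16.0 and 17.2 units. Bloc1s4 lay at 23.1 and 21.9 units on native and at 17.6 and 0 on MMP13-treated matrix, where 0 reads allow up to 5.04 units. Its fold rested on that library, and was -0.33 without it (adjusted p = 0.996), and edgeR gave it an adjusted p of 0.54. Ahnak (-0.50) and the nucleoside diphosphate kinase gene Nme2 (-0.45) were abundant genes with small folds.

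In this comparison 2 of 21 lists passed by camera, in the higher direction. In the oxidative stress list (adjusted p = 5.7e-12), 4 of 16 members passed, Hmox1, Prdx1, Txn1 and Ftl1, and 7 when adjusted over the list alone. The list's adjusted p was 0.50 with an estimated correlation and 2.9e-04 without Hmox1. Txnrd1, the thioredoxin reductase gene, had a log2 fold of 0.63 and did not pass by limma (adjusted p = 0.080), but did by edgeR (0.0451) and DESeq2 (0.0328). In the ribosomal protein list (adjusted p = 0.0014), 2 of 33 members passed, Rpl7 and Rpl35. The list's adjusted p was 0.68 with an estimated correlation and 0.36 without MMP13 replicate 1. Adjusted over the list alone, 6 were higher and 2 lower, and the median log2 fold was 0.14. Rps24 (0.84, adjusted p = 0.0536) and Rps14 (0.85, adjusted p = 0.22) did not pass by limma, while Rps24 did by edgeR (0.0198) and DESeq2 (0.0328). Over all alternatives the adjusted p ran from 2.1e-12 to 0.56 for the oxidative list and from 1.1e-04 to 0.68 for the ribosomal list. Fry called no list. The Rn45s share was 0.83% on MMP13-treated matrix against 0.320% on native, in the same direction as both lists. In the immediate-early list 3 of 22 members passed, and the list did not (adjusted p = 0.34). The other 18 lists had adjusted p of at least 0.30.

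At an unadjusted p under 0.05, 586 genes differed on MMP13-treated matrix. By edgeR 26 genes were higher and 6 lower, of which 20 and 5 were shared with limma. DESeq2 called 21 higher and 5 lower, and limma without its trend called 0. DESeq2's own filter left 858 genes to adjust over here and 14735 in each of the other comparisons, so its counts cannot be set side by side. TMM factors from all genes gave 7 higher and 1 lower. The count of higher genes was 5 without MMP13 replicate 1, 7 without MMP13 replicate 2, 12 without either MMP1 library, 6 without native replicate 1 and 30 without native replicate 2. The count of lower genes was 24 without MMP13 replicate 1, 0 without MMP13 replicate 2, 3 without MMP1 replicate 1, 2 without MMP1 replicate 2, 0 without native replicate 1 and 5 without native replicate 2. Among the 30 calls, those of Hmox1 and Rn45s held without each of the 6 libraries in turn, those of Prdx1, Rn28s and Rpl7 in 5 of these fits, and those of Fam65b, Rpl41 and Ubl3 in 4. Ier2, Ier3, Rpl35 and Txn1 held in 3, and Akr1b8, Ftl1, Mip, Mmp9, Nfat5 and Vps25 in 2. Bloc1s4, Junb, Ppp6r1, Rab18, Rpl37a with its pseudogene entry, Slc38a2 and Sqstm1 held in 1, and Ahnak, Hspb1, Nme2 and Ppm1g in 0. Without native replicate 1 the log2 fold was 0.85 for Ier2 and 0.43 for Txn1, and without MMP13 replicate 2 it was 0.091 for Mip.

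**Figure D2:**
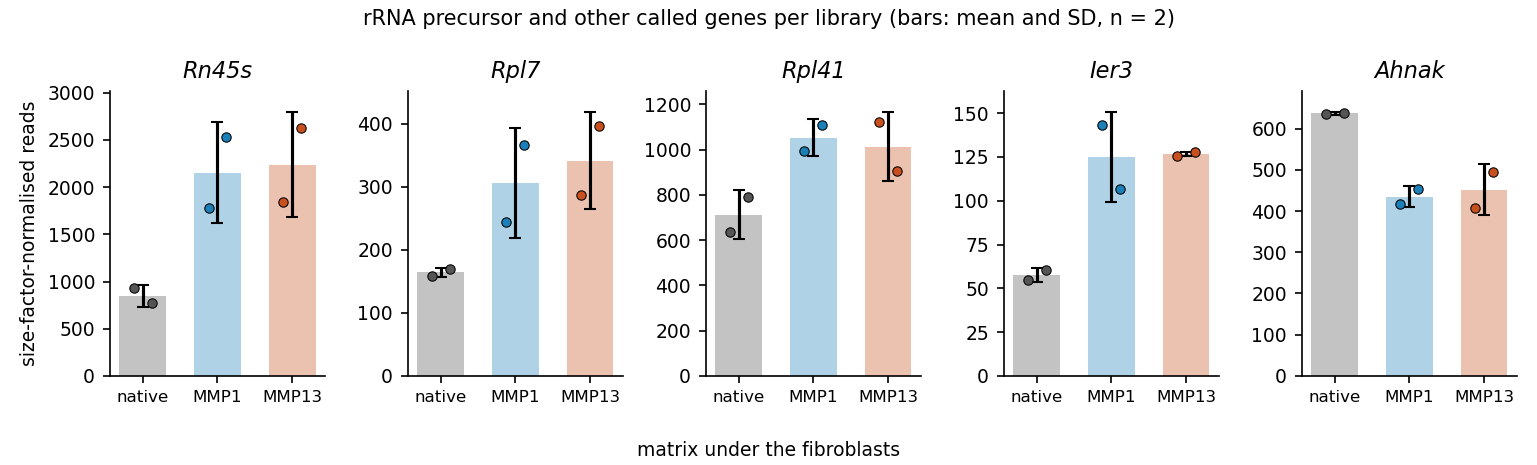
Size-factor-normalised reads (vertical axes, linear from 0) of the ribosomal RNA precursor entry Rn45s, the ribosomal protein genes Rpl7 and Rpl41, the early gene Ier3 and Ahnak on each matrix. Points are libraries, bars are means and whiskers the SD (n = 2). Rn45s lies at 927 and 768 units on native matrix and between 1777 and 2631 units in the 4 libraries of the degraded matrices, and Ahnak lies lower on both degraded matrices than on native.

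Genes of the matrix itself, its turnover and its sensing did not pass as lists in either comparison with native. The lists were structural ECM, collagen processing, ECM proteolysis, matrix receptors, focal adhesion, actin and SRF targets, YAP targets and TGF-beta targets. Of their members, Mmp9 passed by limma, as 1 of 16 in the ECM proteolysis list on MMP13-treated matrix, a call lost without each of 4 libraries in turn and by edgeR (adjusted p = 0.109). Fibronectin Fn1 had a log2 fold of -0.40 on MMP1-treated (adjusted p = 0.13) and -0.37 on MMP13-treated matrix (adjusted p = 0.16). Integrin beta 1, Itgb1, had one of -0.29 and -0.43 respectively, and the collagen chaperone Serpinh1 0.35 and 0.45 (adjusted p = 0.27 and 0.058). Serpinh1 passed on MMP13-treated matrix by edgeR (adjusted p = 0.0451) and without native replicate 2 (0.0492). With quantile scaling Serpinh1 passed on both matrices (0.0449 and 0.0048), and Fn1 (0.0154) and Itgb1 (0.0447) on MMP13-treated matrix. The membrane collagenase Mmp14 had a log2 fold of 0.86 on MMP1-treated matrix (adjusted p = 0.16). The cells' own Mmp13 transcript was at 99.6 ± 5.3 units on native, 70.5 ± 9.7 on MMP1-treated and 63.3 ± 3.1 on MMP13-treated matrix (adjusted p = 0.65 and 0.47 against native). Mmp3 had between 1 and 4 reads per library and was not tested. Col1a1 was at 1972 ± 202 units on native, 2072 ± 168 on MMP1-treated and 2239 ± 53.3 on MMP13-treated matrix, and its sign turned with quantile scaling. For Timp1 the log2 fold was 0.11 (95% interval -0.23 to 0.44) on MMP1-treated and -0.08 (-0.41 to 0.26) on MMP13-treated matrix. For Acta2 it was 0.87 (0.19 to 1.56) and 0.78 (0.09 to 1.46), with native libraries at 17.0 and 48.3 units and adjusted p of 0.39 and 0.51. Both Acta2 intervals take their error from the trend, and with native libraries this far apart they are too narrow. Neither Ctgf (0.45 and 0.46) nor Cyr61 (-0.68 and -0.62) passed. Inflammatory, interferon, cell cycle, p53, glycolysis, cholesterol, ER stress, heat shock and oxidative phosphorylation lists did not pass either. Simulations for MMP1 against native recovered 3 of 200 genes changed 2-fold, so a gene that did not pass may still have changed 2-fold. The list tests were not simulated. The list of mitochondrially encoded transcripts had no matched member and was not analysed here.

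The direct comparison of MMP1-treated with MMP13-treated matrix gave 0 higher and 3 lower genes. Hmox1 was lower on MMP1-treated matrix, 328 ± 37.9 against 792 ± 60.7 units (log2 fold -1.27, SE 0.16, adjusted p = 2.5e-12). Osbpl5, which encodes an oxysterol-binding-protein-related lipid transfer protein, lay at 10.2 and 12.0 units on MMP1-treated and 45.6 and 53.7 on MMP13-treated matrix (log2 fold -2.06, SE 0.45, adjusted p = 0.014), with native libraries between them at 20.7 and 29.4. The F-box gene Fbxo22 lay at 8.84 ± 4.02 against 38.2 ± 12.4 units (SD, n = 2 each; log2 fold -2.02, adjusted p = 0.047). Of genes higher on MMP1-treated matrix, Gins4 (log2 fold 2.17, adjusted p = 0.094), Bloc1s4 (2.31, adjusted p = 0.17) and Ubl3 (1.73, adjusted p = 0.17) came next and did not pass. Without MMP13 replicate 1 they did (adjusted p = 0.0060, 3.4e-05 and 0.0162). The oxidative stress list was lower on MMP1-treated matrix by camera (adjusted p = 0.0026), with 1 of 16 members past the threshold, Hmox1, and 2 adjusted over the list alone, Hmox1 and Txnrd1 (-0.57). Mt2A had a log2 fold of 0.58 and Ftl1 of -0.40. The list's adjusted p was 0.93 with an estimated correlation, 0.67 without Hmox1, 0.0504 without MMP1 replicate 1, 0.21 without MMP1 replicate 2 and 0.70 without MMP13 replicate 1, over a range of 5.9e-06 to 0.93. The Rn45s share was 0.80% on MMP1-treated and 0.83% on MMP13-treated matrix. The other 20 lists had adjusted p of at least 0.67.

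At an unadjusted p under 0.05, 380 genes differed between the degraded matrices, 192 of them higher on MMP1-treated matrix. By edgeR 0 were higher and 2 lower, by DESeq2 0 and 1, and limma without its trend called 0. Without MMP13 replicate 1, 23 genes were higher, and without any other library 0 were. The call of Hmox1 held without each library in turn. Osbpl5 had an adjusted p of 1.0 without MMP13 replicate 2, 0.13 without MMP1 replicate 1, 0.0593 without MMP1 replicate 2 and 0.073 without native replicate 2. Fbxo22 had 1.0 without MMP13 replicate 2, 0.53 without MMP1 replicate 2, 0.31 without native replicate 1 and 0.17 without native replicate 2, and edgeR gave it 0.099. Of the 12 alternatives that kept all libraries, Fbxo22 held its call in 1, with genes of identical reads counted once, and its adjusted p in the others ran upward from 0.0553 with TMM scaling. Osbpl5 also lost its call with only the 2 groups compared (adjusted p = 0.073), by DESeq2 (0.96) and without the limma trend (0.82).

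Both degraded matrices shared 7 of their higher genes, Hmox1, Ier3, Mip, Rn45s, Rpl41, Rpl7 and Txn1, and 1 lower gene, Ahnak. Independent lists of these lengths would share 0.027 higher and 0.0014 lower genes, and simulated unchanged groups against the same controls shared 0 in either direction in each of 100 draws. Those groups gave at most 1 call per draw in either comparison, so that simulated overlap could hardly exceed 0, and what the shared controls add to the overlap was not measured. The shared lower gene rested on an adjusted p of 0.0499 for Ahnak on MMP13-treated matrix. With all libraries kept, the shared lower count was 3 with quantile scaling, 2 at an adjusted p under 0.1, 1 by edgeR and 0 in the other 10 alternatives. It was 0 with a library left out, except without native replicate 2, where 2 other genes, Hnrnpa2b1 and Slc38a2, were shared. The shared higher count was 3 without MMP13 replicate 2, MMP1 replicate 2 or native replicate 1, 4 without MMP13 replicate 1 or MMP1 replicate 1, and 12 without native replicate 2, with Hmox1 and Rn45s shared each time. It was 0 without the limma trend, 1 by DESeq2, 2 with TMM factors from all genes and 3 with only the 2 groups compared. Across the 7284 tested genes the log2 folds of both comparisons correlated with r = 0.56, and 70.8% had the same sign. Because both use the same 2 native libraries, simulated unchanged groups already gave r = 0.45 and 65.3% of the same sign. The covariance was 0.32, against 0.13 in the simulation, an excess of 0.19. With the stricter filter the covariance was 0.147, against 0.0738 in the simulation, an excess of 0.0736. The simulation drew every gene with 1 dispersion, so where genes vary more its covariance is too low and the excess too large. Without native replicate 1 or 2 the covariance was 0.396 or 0.674, against 0.207 or 0.306 in the simulation. The excess is thus by itself no measure of a shared response. The controls were not split, with 1 native library for each comparison. Part of the overlap and of the excess in the correlation and the covariance may therefore come from the shared controls. With each library left out in turn the correlation ran from 0.43, without MMP13 replicate 1, to 0.73, without native replicate 2, where unchanged groups simulated in the same way gave 0.33 and 0.66. The excess of the covariance over its simulated value ran from 0.16, without MMP1 replicate 1, to 0.37, without native replicate 2.

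**Figure D3:**
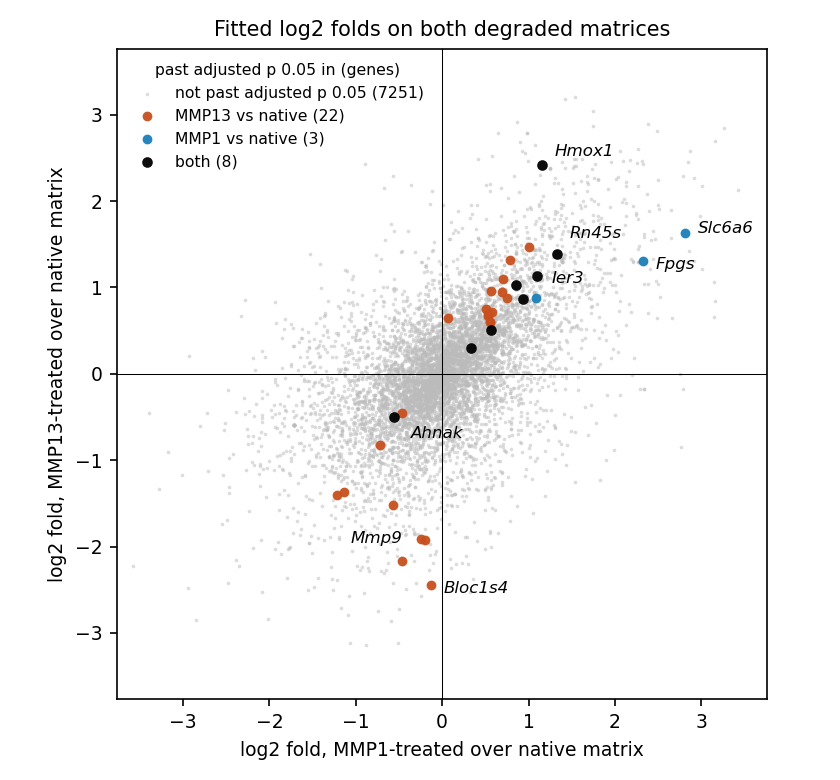
Fitted log2 folds of the 7284 tested genes on MMP1-treated over native matrix (horizontal axis) and MMP13-treated over native matrix (vertical axis). Coloured points passed an adjusted p of 0.05 in 1 comparison and black points in both. Hmox1 lies at 1.15 and 2.42 and Rn45s at 1.33 and 1.38, and the shared native libraries alone gave r = 0.45 in simulations, against 0.56 here.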

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

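The tests of sequencing depth, of metal carry-over on MMP1-treated matrix and of short genes with the span trend removed, and the list without Hmox1, were chosen only after the result was seen. The tests of metal carry-over on MMP13-treated matrix, of scaling and of short genes as such were written before their values were seen, on patterns already noticed in the same data.

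The responses to the degraded matrices differed, by the direct limma test, for 3 genes, given as the log2 fold of MMP1-treated over MMP13-treated matrix. For Hmox1 it was -1.27, with adjusted p between 2.4e-14 and 0.82 over the alternatives, the highest without the limma trend. Osbpl5 had a log2 fold of -2.06 and lost its call without MMP13 replicate 2 (adjusted p = 1.0), without MMP1 replicate 1 (0.13), without MMP1 replicate 2 (0.0593) and without native replicate 2 (0.073), over a range of 0.012 to 1.0. Fbxo22 had a log2 fold of -2.02 and an adjusted p of 1.0 without MMP13 replicate 2, 0.53 without MMP1 replicate 2, 0.31 without native replicate 1 and 0.17 without native replicate 2, over a range of 0.026 to 1.0. Fbxo22 also lost its call with TMM (0.0553) and quantile scaling (0.11), no filter (0.0687), the stricter filter (0.0897), a pseudocount of 5 (0.0686), the replicate block (0.0732) and by edgeR (0.099).

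By camera the oxidative stress list was higher on both degraded matrices, Hmox1 most of all. However, 2 of 16 members passed on MMP1-treated and 4 of 16 on MMP13-treated matrix. Positive log2 folds were seen for 10 and 11 of the 16 members, with list medians of 0.25 and 0.22. The list's adjusted p was 0.71 and 0.50 with an estimated correlation and 0.58 and 0.56 by fry. If metal had been carried over with the enzyme, the metallothionein genes Mt1a and Mt2A should rise by an average log2 fold of at least 1. On MMP13-treated matrix the average was 0.03 with an upper 95% limit of 0.614 (0.819 with fully correlated errors). This argues there only against carry-over strong enough to raise both genes that far. On MMP1-treated matrix the average was 0.40 with an upper limit of 0.982 (1.19 with fully correlated errors), which leaves carry-over open. These limits take their error from the trend, and Mt1a had between 9 and 25 reads per library. Whether either gene responds to metal in these cells by 4 h was not tested, nor were other reagents. If sequencing depth were the cause, the mean of all 16 members should lose its difference from native with log2 depth in the fit, but with 6 libraries the intervals were too wide to decide, at 0.39 without and 0.44 with depth (95% interval -0.064 to 0.943) on MMP13-treated and 0.19 and 0.31 (-0.24 to 0.851) on MMP1-treated matrix, after 2 earlier forms of the test on the 4 called members were set aside. A response to the degraded matrix stays open as an untested hypothesis, as does an RNA quality difference, of which the Rn45s share (0.320% against 0.80% and 0.83%) may be a sign.

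Ribosomal protein genes were higher as a list on both degraded matrices, though not with an estimated correlation (adjusted p = 0.70 and 0.68). A scaling error of all abundant genes should move other abundant genes alike, but the median log2 fold of the ribosomal list exceeded that of 200 other abundant genes by 0.243 (bootstrap 95% interval 0.033 to 0.375) on MMP1-treated and by 0.155 (0.030 to 0.333) on MMP13-treated matrix, which argues against it. Shorter genes did tend to have higher folds (Spearman's rho with span -0.18 and -0.15 on MMP1-treated and MMP13-treated matrix, and -0.14 and -0.13 without ribosomal protein and oxidative stress genes), and although the list exceeded 208 other short genes of like level by 0.247 (0.039 to 0.369) and 0.132 (0.0095 to 0.318), these had a longer median span, 6415 against 3526 bases, so that comparison does not settle it. With their span trend removed the excess was 0.19 (0.017 to 0.328) on MMP1-treated matrix and 0.095 (-0.023 to 0.271) on MMP13-treated matrix. Genomic span alone thus did not remove the excess on MMP1-treated matrix, while on MMP13-treated matrix the interval reached below 0. Transcript length was not tested, so short transcripts stay open as a cause on both. These intervals resample genes, which are not independent, and leave open that the libraries differ by RNA quality or that reads of ribosomal protein copies were split unevenly, which may account for members that moved apart, such as Rpl7 and Rps18.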

How the results depend on the processing

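Comparisons with edgeR and DESeq2, TMM factors from all genes, genes of identical values counted once, the list without Hmox1, and quantile scaling of the lists and the shared response were chosen after seeing the data. Hmox1 kept its call in all 3 comparisons under 11 of 12 alternatives and without each of the 6 libraries. Over the 93 folds of named genes, 1192 of 1570 values under an alternative kept direction and side of the threshold, 342 lost the call in the same direction, 18 gained one and 18 changed sign. Many of these folds had not passed, and they count as kept while they stay uncalled. The 342 losses come from called folds alone, so these totals do not give the share of calls kept.

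Without the limma trend, all 6 counts of genes were 0. With only the 2 groups compared, 5 genes were higher and 0 lower on MMP1-treated than native matrix, 6 and 0 on MMP13-treated, and 1 was lower on MMP1-treated than MMP13-treated. TMM factors from all genes gave 2 and 0 for MMP1 against native, and 7 and 1 for MMP13. DESeq2 gave 1 and 0 for MMP1 against native, 5 lower for MMP13, and 1 lower for MMP1 against MMP13. EdgeR gave 6 lower for MMP13. TMM scaling gave 13 higher and 4 lower for MMP13, no filter 12 and 1, the stricter filter 13 and 2, and a pseudocount of 5 gave 5 lower. For MMP1 against native, the lower count was 0 without a filter and with the stricter filter, and 3 with quantile scaling and at an adjusted p under 0.1, where 1 gene was higher on MMP1-treated than MMP13-treated matrix. No filter adds genes to the multiple-testing adjustment, and the cause of the other changes was not tested.

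Leaving out 1 library at a time, a lone library being assumed to vary like the other groups, gave 3 to 15 higher and 0 to 4 lower genes for MMP1 against native, 5 to 30 and 0 to 24 for MMP13 against native, and 0 to 23 and 1 to 4 for MMP1 against MMP13. The lists past the threshold numbered 1 to 3 of 3, 1 to 2 of 2, and 0 to 1 of 1. With an estimated correlation and with fry all 3 numbers were 0, and without Hmox1 they were 1, 2 and 0. The correlation of both responses was 0.62 with the stricter filter, against 0.47 in simulated unchanged groups, and 0.43 to 0.73 with a library left out, against 0.33 to 0.66.

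Deviations of same-numbered libraries correlated across tested genes with r of 0.01, -0.07 and -0.04, so no pairing by replicate number was seen. The median level of tested genes was 13.3 units, where read noise is large, so a batch shared by abundant genes is not excluded. With the replicate block the lower count for MMP13 went from 10 to 5 and the higher count from 20 to 16, and Fbxo22 lost its call for MMP1 against MMP13 (adjusted p = 0.0732); no list call changed. With genes of identical reads counted once, 16 higher and 7 lower genes were left for MMP13 against native, and no call was lost in the other comparisons.

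The 18 sign changes were in comparisons where the gene had not passed. With a library left out, the log2 fold of Timp1 ran from -0.086 to 0.30 (MMP1 over native), -0.23 to 0.079 (MMP13 over native) and -0.0084 to 0.37 (MMP1 over MMP13). It ran from -0.032 to 0.18 for Col1a1 (MMP1 over native) and -0.94 to 0.45 for Mmp9 (MMP1 over native). For MMP1 over MMP13 it ran from -0.15 to 0.34 for Acta2, -0.46 to 0.43 for Ctgf and -0.46 to 0.34 for Cyr61. Quantile scaling gave Col1a1 -0.16 in both comparisons with native, and Ctgf (MMP1 over MMP13) was 0.048 with edgeR and 0.047 with DESeq2. At these depths, with 2 libraries per group, simulations recovered 1.5% of genes changed 2-fold and 64% of those changed 4-fold for MMP1 against native. The depth was not varied.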

Other observations

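The relation of fold to gene span was computed only after the data were seen. Among 478 tested genes at a mean of at least 100 units, shorter genes tended to have higher folds on both degraded matrices. Spearman's rho of log2 fold and genomic span was -0.18 for MMP1 over native (permutation p = 1e-04, the smallest that 10000 permutations can give, adjusted over 3 relations 0.0003), -0.15 for MMP13 over native (p = 0.0007, adjusted 0.001) and -0.01 for MMP1 over MMP13 (p = 0.89, adjusted 0.89). Without ribosomal protein and oxidative stress genes (418 left) rho was -0.14, -0.13 and 0.02. These are correlations across genes, which are not independent replicates, and the 2 relations with native share the native libraries. Ahnak, lower on both matrices, and Txn1, Ier3 and Rpl41, higher on both, are examples named after their values were seen.

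Mip, which encodes the lens aquaporin, was the most abundant entry of the table, at a mean of 6230 units and 2.25% of all reads, above Actb at 1.57%. It lay between 4880 and 7543 units in every library. The origin of the reads counted under Mip was not checked here, since no annotation of the build rn5 was used. Other marker lists stayed low, and the most abundant marker of each was, for example, Scx for tenocytes (mean 37.6 units), Csf1r for leukocytes (15.7), Egfl7 for endothelium (27.0) and Acan for cartilage (22.1).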
